A study of Mus musculus with 2 samples.

How the data were processed

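MicroRNA-seq libraries were made from total RNA of hippocampus from female B6CASTF1/J mice at 10 days of age, and small RNA below 30 nt was sequenced, per the labels. The series holds 2 samples of 1 group. The labels call them biological replicates 1 and 2 and name a different set of 3 females for each, under a shared donor entry, so the spread between them covers animals, dissection and library preparation together. Both samples were used. A chi-square statistic of 523 per gene, where counting error alone gives about 1, excluded that they were copies of 1 library.

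The deposited values are raw read counts per microRNA gene, in 1 file per library, and replicates were not pooled in them. Per the file notes deposited with each sample, the genome build was mm10 and the annotation GENCODE M21. The aligner, the counting program and the read filters are not given in the sources used here. Each file gives counts without regard to strand, counts on the sense strand and counts on the opposite strand. The column that held more counts on gene rows was taken as the sense strand for all genes in both libraries, and sense counts were used throughout. All 2202 gene identifiers, version included, matched microRNA genes of GENCODE M21, which annotates 2207, and symbols, positions and host genes were taken from that annotation.

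The files also hold 4 rows of reads without a gene, which were left out of library sizes and tests. In replicates 1 and 2, 43.2% and 39.3% of all reads matched several places, 14.2% and 18.0% were unmapped, and 6.16% and 5.17% lay outside microRNA genes. Sense counts on microRNA genes made up 36.4% of 15058588 reads in replicate 1 and 37.6% of 9483409 reads in replicate 2. A read that matches several places is in no gene count, which can lower the values of microRNAs with near-identical copies. In the counts without regard to strand, a read over genes annotated on both strands is ambiguous and also in no gene count.

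Values per gene were sense counts divided by the library's sense counts on microRNA genes and multiplied by 1000000 (CPM). A gene was called detected with at least 10 counts in each library. Shares are percents of the sense counts on microRNA genes. Their exact Clopper-Pearson intervals at 95%, and the upper limit of 3 counts for a count of 0, cover counting error only, since reads without molecular identifiers are not independent molecules. At these depths the interval of the top-10 share ran from 47.26% to 47.34% in replicate 1 and from 50.06% to 50.17% in replicate 2, so the spread between libraries set the precision.

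The libraries were scaled with TMM factors from edgeR (0.979 and 1.02). Pearson and Spearman correlations used log2(CPM + 1) over detected genes, with a bootstrap over genes of 1000 resamples. The common biological coefficient of variation came from estimateDisp of edgeR with an intercept only, with 100 bootstrap resamples of genes. Each detected gene was compared between the libraries with a two-sided exact binomial test against the share of the scaled library sizes, with Benjamini-Hochberg adjustment at 0.05. Ratios are replicate 2 over replicate 1 and add 0.5 counts to each library. Genes within 10 kb of each other on a strand were joined to clusters. The longest stretch that a gene shares with any other microRNA gene was found from the annotated transcript sequences. On counts simulated from the means and library sizes of these genes, with counting error only, the binomial test called 88.0% of genes changed 2-fold. It called 100.0% of those with a mean of at least 100 counts, 52.0% of genes changed 1.2-fold and 2.62% of unchanged genes. These rates leave out the spread between libraries beyond counting error, which the real libraries have. A coefficient of variation of 0.4, simulated separately, was recovered as 0.395.

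The 16 gene lists, the tests of the report, the rule for named genes and the alternatives were fixed before the data were examined, except the minimum of 5 CPM and the search of transcripts for shared stretches, which were added afterwards. The tests of explanations in the closing section were also set after the data were first examined. Named genes are the 20 with the highest mean CPM, the up to 4 most abundant members of each list, the 5 highest and 5 lowest ratios among detected genes with a mean of at least 100 counts, the 3 genes with the most antisense counts, and the copies of Mir124, Mir9, Mir128 and let-7. Lists match gene symbols by microRNA number, and 1 gene, Mir134, is in 2 lists. Of 9 members planned for the mir-17-92 and mir-106b-25 list, 7 matched a symbol, and Mir18 and Mir92-1, the other 2, are outside the list as computed. The lists describe enrichment known from other work, and many members are also expressed outside the named cell type.

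Alternatives were other count minimums, counts without regard to strand, DESeq2 size factors or library totals in place of TMM, a pseudocount of 0.1 CPM, a minimum of 5 CPM, all reads as the denominator, the most abundant gene left out, each replicate left out and a cluster distance of 50 kb. A planned search for unique 20-mers in the genome was replaced by the comparison of transcript sequences, because no genome sequence was used here. Software was R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.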

Results

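MicroRNA-seq was performed on hippocampus of female mice at postnatal day 10, an age at which neurons of this region are still forming synapses. The mice were B6CASTF1/J, first-generation hybrids of the inbred strains C57BL/6J and CAST. The series holds 1 group of 2 biological replicates, and each label names a separate set of 3 females. Small RNA below 30 nt was sequenced, and counts were given for 2202 annotated microRNA genes. Replicate 1 held 5479267 sense-strand counts on these genes and replicate 2 held 3563226. With a single group there was no comparison between conditions, so abundance, the composition by gene group and the spread between the 2 libraries were measured. Unless stated otherwise, values are the mean ± SD of 2 libraries in counts per 1000000 sense counts on microRNA genes (CPM), and coordinates are those of GRCm38 (mm10) with the GENCODE M21 annotation.

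Among reads assigned to a gene, the let-7 family and the imprinted Dlk1-Dio3 cluster held the largest shares of the 16 gene lists. A further 41.3% ± 2.81 of all reads (SD, n = 2) matched several places and are in no gene count, so the ranks below hold for assigned reads. Reads assigned to let-7 genes made up 9.59% of all reads, and the let-7 part of the reads that matched several places is not known. Mirlet7b was the most abundant gene at 101435 ± 3774 CPM (SD, n = 2), followed by Mirlet7i at 61279 ± 6764 CPM, Mir139 at 59441 ± 10236 CPM, Mir99a at 53513 ± 7490 CPM, Mirlet7g at 49733 ± 1710 CPM and Mir127 at 49359 ± 14139 CPM. Mirlet7b was the highest gene in both libraries. The order of the next genes was not resolved with 2 libraries, since Mirlet7i stood at 66062 CPM in replicate 1 and 56496 CPM in replicate 2 and Mir139 at 52203 and 66679 CPM. The 10 most abundant genes held 48.7% ± 1.99 of the counts (SD, n = 2), and 4 of them were let-7 members and 3 were Dlk1-Dio3 members. The 20 most abundant genes held 63.9% ± 0.259 and the top 100 held 93.9% ± 0.0355.

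**Figure D1:**
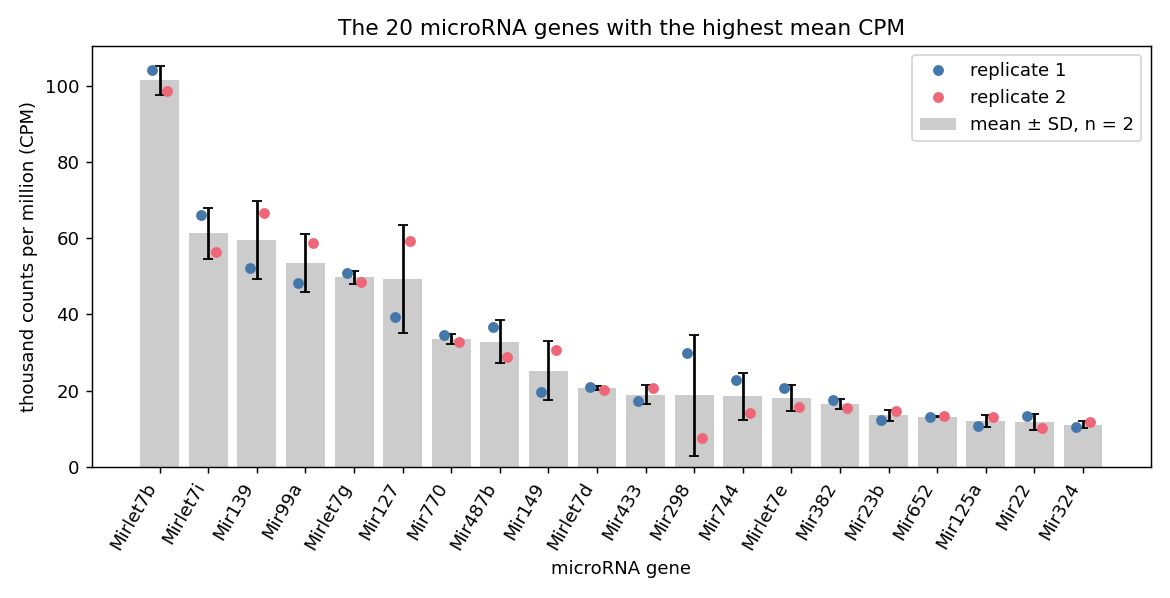
Bars give the mean of the 20 most abundant microRNA genes in CPM, with the axis in units of 1000 CPM, error bars the SD of 2 libraries and points each library. Mirlet7b stands highest at a mean of 101435 CPM, and Mir298 has the widest relative gap, with 29970 CPM in replicate 1 and 7502 CPM in replicate 2.

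The leading genes lie in several kinds of annotated locus. Mirlet7b (ENSMUSG00000065564.1, chromosome 15, 85707319 to 85707403, plus strand) lies in an exon of the long non-coding gene Lncppara, together with Mirlet7c-2. Mirlet7i (chromosome 10, 122985640 to 122985724) lies in an exon of the non-coding gene D630033A02Rik. Mir139 (ENSMUSG00000065446.1, chromosome 7, 101475376 to 101475443) lies in an intron of Pde2a, which encodes a phosphodiesterase that degrades cyclic nucleotides. Mir99a (chromosome 16, 77598936 to 77599000) and Mirlet7c-1 lie in an intron of Mir99ahg. Mirlet7g (chromosome 9, 106178840 to 106178927) lies in an intron of Wdr82. Mir149 (chromosome 1, 92850378 to 92850443), at 25214 ± 7726 CPM, lies in an intron of Gpc1, which encodes a heparan sulfate proteoglycan. The remaining genes among the top 20 outside the let-7 and Dlk1-Dio3 groups were Mir298, at 18736 ± 15887 CPM, Mir744 in an intron of Map2k4, at 18540 ± 6139 CPM, Mir23b at 13494 ± 1542 CPM, Mir652 at 13206 ± 85.7 CPM, Mir125a at 11945 ± 1588 CPM, Mir22 at 11778 ± 2134 CPM and Mir324 at 11119 ± 845 CPM.

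Of the 2202 genes, 19.5% were detected, with at least 10 counts in each library, and 1385 had no sense count in either library. Where reads have a unique place, a count of 0 allows a level of up to 0.548 CPM in replicate 1 and 0.842 CPM in replicate 2. Reads that match several places are in no gene count, so a 0 sets no such limit for near-identical copies. The number detected depended on the minimum, since 670 genes had at least 1 count in each library and 267 had at least 100. Mean levels of at least 1000 CPM were reached by 115 genes and levels of at least 10000 CPM by 22 genes. Of 1021 predicted genes with a symbol that starts with Gm, 8 were detected.

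The let-7 family, whose mature forms accumulate as cells leave the cell cycle and differentiate, held 26.0% ± 1.62 of the counts (SD, n = 2; replicate 1, 27.1%; replicate 2, 24.8%). All 12 members, Mir98 included, were detected. Mirlet7d reached 20615 ± 482 CPM and Mirlet7e 18109 ± 3498 CPM. Mirlet7b held 38.9% of the family's counts, and the family's share was 17.6% with this gene left out of the list and the total. Levels of the numbered copies were lower than that of Mirlet7e, and Mir98, at 2379 CPM, lay below the numbered copy Mirlet7c-2. Mirlet7c-2 stood at 3100 ± 46.7 CPM, Mirlet7f-2 at 1429 ± 68.9 CPM, Mirlet7c-1 at 971 ± 95.4 CPM, Mirlet7a-1 at 280 ± 36.2 CPM, Mirlet7a-2 at 109 ± 26.3 CPM and Mirlet7f-1 at 65.4 ± 4.34 CPM. Reads that matched several places were not assigned to any gene in these counts, so the levels of genes with near-identical copies are uncertain.

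The Dlk1-Dio3 microRNAs of chromosome 12, which are transcribed from the maternal allele, held 21.97% ± 0.858 of the counts (SD, n = 2; replicate 1, 21.4%; replicate 2, 22.6%), and 47 of 50 list members were detected. Mir127 (chromosome 12, 109592846 to 109592915) led, followed by Mir770 (chromosome 12, 109563692 to 109563785, in an exon of the non-coding gene Meg3) at 33643 ± 1338 CPM, Mir487b (chromosome 12, 109727333 to 109727414) at 32842 ± 5631 CPM, Mir433 at 18950 ± 2507 CPM and Mir382, in an exon of Mirg, at 16501 ± 1392 CPM. When all microRNA genes within 10 kb on the plus strand were joined, including some outside the list, this region held 3 groups. The group from 109563692 to 109595388 held 14 genes, Mir127, Mir770 and Mir433 among them, and 11.5% ± 1.59 of the counts. The group from 109709060 to 109747960 held 39 genes, 35 of them detected, and 10.0% ± 0.719 of the counts. A smaller group between them, from 109611500 to 109618336, held 4 genes, Mir370 and Mir341 among them, and 0.563% ± 0.0164 of the counts.

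**Figure D2:**
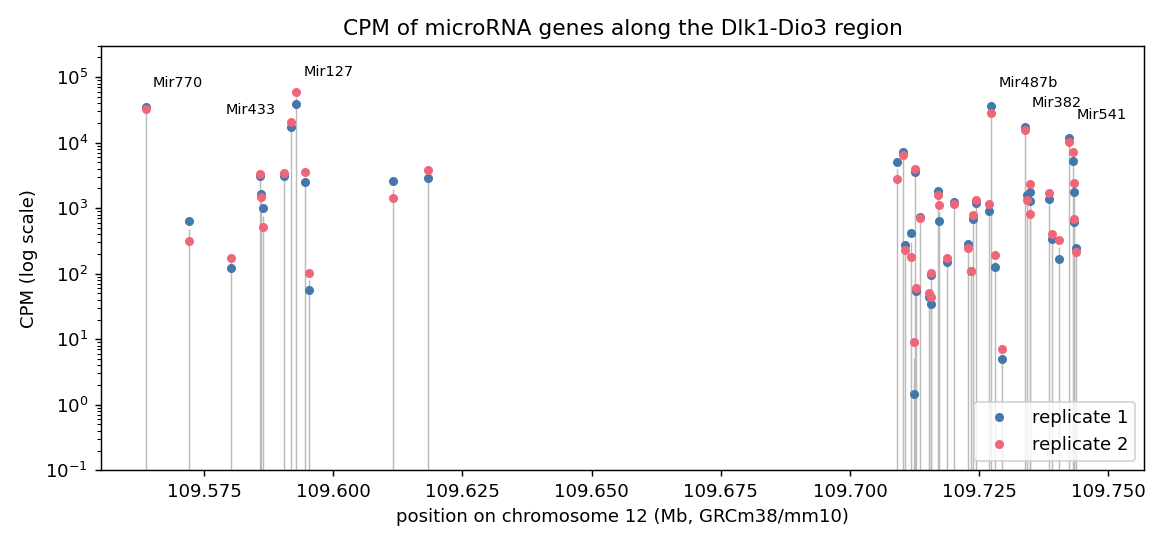
Each point is a counted Dlk1-Dio3 list member in 1 library at its position on chromosome 12, with CPM on a log axis and grey lines that reach the mean. The 5 most abundant members lie in the outer groups of genes, Mir770, Mir433 and Mir127 in the left one and Mir487b and Mir382 in the right one.

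Clusters were common among the abundant genes. Neighbours within 10 kb on a strand formed clusters of 479 genes in all, with 59.4% ± 0.301 of the counts (SD, n = 2). Besides the Dlk1-Dio3 groups, the leading clusters were Mirlet7b with Mirlet7c-2 at 10.5% ± 0.373, Mir99a with Mirlet7c-1 at 5.45% ± 0.759 and Mirlet7e with Mir125a and Mir99b on chromosome 17 at 3.95% ± 0.259.

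MicroRNAs described as enriched in neurons held 3.23% ± 0.244 of the counts (SD, n = 2), and 18 of 21 members were detected. Mir132, whose transcription follows neuronal activity, was the most abundant at 8030 ± 685 CPM. Mir128-1, in an intron of R3hdm1, reached 6638 ± 435 CPM, Mir138-1, which limits dendritic spine size, 5024 ± 1029 CPM, and Mir137 4273 ± 522 CPM. Mir128-2, in an intron of Arpp21, stood at 2397 ± 62.7 CPM. The copies of Mir124 and Mir9, described as abundant in brain, had few counts. Mir124a-1 had 10 and 20 counts in replicates 1 and 2, Mir124a-2 had 5 and 3, and Mir124a-3 had 9 and 5. Mir9-1 stood at 16.1 ± 10.5 CPM, Mir9-2 at 3.19 ± 0.140 CPM and Mir9-3 at 58.3 ± 14.6 CPM (SD, n = 2). Each of these 6 copies shares a stretch of at least 26 nt with another microRNA gene. Reads without a unique place are not in these counts, so the levels of Mir124 and Mir9 were not determined. Copies of Mir128, Mir138, Mir129 and Mir218 share 22 to 26 nt with another microRNA gene, so the neuron share covers only reads with a unique place.

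The lists of other brain and vascular cell types held smaller shares of the assigned reads. Each list may lose a different part to reads that match several places, so the order of the lists in the tissue was not determined. Oligodendrocyte microRNAs held 0.180% ± 0.0338 (SD, n = 2), with Mir219a-2 at 1004 ± 345 CPM and Mir338, in an intron of Aatk, at 779 ± 5.00 CPM, both known to promote oligodendrocyte differentiation. A further member, Mir219a-1, stood at 18.7 ± 1.89 CPM. Mir219a-1 and Mir219a-2 each share 22 nt with another microRNA gene, so their levels cover only reads with a unique place. Astrocyte microRNAs held 0.271% ± 0.000758, with 8 of 11 members detected. The equal shares hid opposite differences between the libraries, since Mir29a stood at 943 CPM in replicate 1 and 1874 CPM in replicate 2 and Mir21a at 1354 and 441 CPM. Mir29c reached 186 ± 15.6 CPM and Mir193b 118 ± 41.3 CPM. Microglia and myeloid microRNAs held 0.195% ± 0.00217, led by Mir146 at 950 ± 168 CPM and Mir150 at 858 ± 182.9 CPM, with Mir155 at 87.8 ± 5.91 CPM and Mir142, a marker of blood lineage cells, at 38.6 ± 14.9 CPM. Endothelial and vascular wall microRNAs held 1.14% ± 0.0437. Mir126a, which lies within Egfl7 and marks endothelium, reached 8144 ± 224 CPM, and the smooth muscle microRNAs Mir143 and Mir145a reached 3082 ± 196.1 and 220 ± 16.7 CPM. Choroid plexus and ependyma microRNAs held 0.638% ± 0.00169. They were led by Mir449a, of multiciliated cells, at 1930 ± 290 CPM, Mir1298, in an intron of Htr2c, at 1436 ± 19.3 CPM, Mir204, in an intron of Trpm3, at 1427 ± 184 CPM and Mir34c at 1349 ± 51.0 CPM. In the counts made without regard to strand, the oligodendrocyte share was 5.9e-05% and the endothelial share 0.351%, because Mir219a-2, Mir338 and Mir126a have a microRNA gene annotated on the opposite strand.

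**Figure D3:**
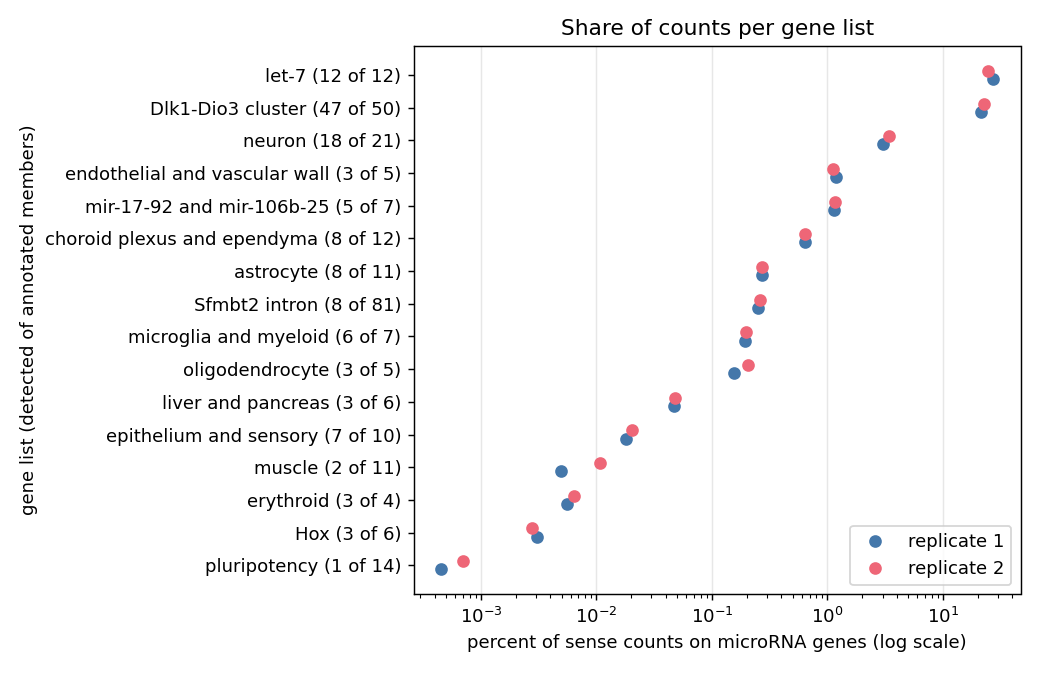
Points give the percent of sense counts on microRNA genes held by each of 16 gene lists in each of the 2 libraries, on a log axis, with the detected and annotated members of each list in parentheses. The let-7 and Dlk1-Dio3 lists lie above 20% in both libraries and the pluripotency list below 0.001%.

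The list of mir-17-92 and mir-106b-25 microRNAs, known from proliferating cells, held 1.14% ± 0.0178 (SD, n = 2), with 5 of 7 matched members detected. Its share is too low for the clusters as a whole, because Mir92-1, at 1358 ± 363 CPM, and Mir18, at 203.6 ± 33.6 CPM, carry other symbols than the list and were left out of it; both were noticed after their values were seen. By position, the Mir17 cluster held 0.607% ± 0.0318 and the Mir93 cluster 0.692% ± 0.0190. Mir93, within Mcm7, reached 5301 ± 15.4 CPM, Mir17 3657 ± 111 CPM, Mir106b 1478 ± 194 CPM and Mir20a 848 ± 99.4 CPM. The list made for the repeat cluster in an intron of Sfmbt2 on chromosome 2, matched by microRNA number, held 0.257% ± 0.00795, with 8 of 81 list members detected and 63 without a count. Of the 81, 71 lie within Sfmbt2 on chromosome 2, and the cluster by position has 119 genes. Its leading members were Mir467d at 1376 ± 166 CPM, Mir669c at 400 ± 39.2 CPM, Mir467e at 336 ± 14.2 CPM and Mir669o at 255 ± 20.7 CPM. Reads that match several places are in no gene count, so the zeros and the share of this repeat cluster do not give its level.

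Lists of microRNAs from other tissues and stages each held under 0.05% of the counts. Liver and pancreas microRNAs held 0.0472% ± 0.000784 (SD, n = 2), of which 84.6% came from Mir375, known from islet and neuroendocrine cells, at 402 ± 22.6 CPM, while the hepatocyte microRNA Mir122 stood at 34.5 ± 0.309 CPM, Mir217 at 29.9 ± 8.10 CPM and Mir216a at 2.98 ± 3.02 CPM. Epithelial and sensory microRNAs held 0.0191% ± 0.00158, with Mir203 at 86.5 ± 31.5 CPM, Mir200c at 33.5 ± 24.9 CPM, Mir429 at 19.4 ± 7.07 CPM and Mir200b at 16.0 ± 2.44 CPM. Muscle microRNAs held 0.00784% ± 0.00407, and 0.00496% without replicate 2. Of 11 members, 5 had no count, Mir1a-1, Mir1a-2, Mir133a-1 and Mir133a-2 among them. Reads that match several places are in no gene count, so these zeros do not show absence. Mir206, of skeletal muscle, had 220 and 346 counts in replicates 1 and 2, and Mir499, Mir208b and Mir208a stood at 4.51 ± 1.62, 2.22 ± 0.0389 and 2.04 ± 1.08 CPM. Erythroid microRNAs, a measure of blood in the tissue, held 0.00599% ± 0.000621, with Mir451a at 30.3 ± 3.60 CPM, Mir486 at 23.2 ± 2.89 CPM and Mir144 at 6.37 ± 0.280 CPM. Without regard to strand the erythroid share was 0.000678%, since Mir451a and Mir486 also have a gene on the opposite strand. Hox cluster microRNAs, of posterior body regions, held 0.00290% ± 0.000210, with Mir10b at 15.8 ± 8.08 CPM, Mir10a at 6.06 ± 1.35 CPM, Mir196b at 4.09 ± 2.95 CPM and Mir615 at 1.58 ± 0.942 CPM. Pluripotency microRNAs held 0.000579% ± 0.000173. Of 14 members, Mir302d alone was detected, with 14 and 13 counts, while Mir302a had 7 and 2, Mir294 had 0 and 5 and Mir302b had 1 and 3.

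The 2 libraries ranked the detected genes alike, and single genes still differed by more than counting error. Across the detected genes, Pearson's r of log2(CPM + 1) was 0.984 (bootstrap interval over genes 0.980 to 0.988) and Spearman's rho 0.978, as descriptions across genes, which are not independent replicates. The biological coefficient of variation estimated by edgeR was 0.311 (bootstrap interval over genes 0.281 to 0.340). Its interval does not cover the uncertainty from having only 2 libraries. The median absolute log2 ratio of replicate 2 to replicate 1 was 0.33. By a two-sided exact binomial test at a Benjamini-Hochberg adjusted p of 0.05, 263 of the detected genes (61.3%) differed beyond counting error, 123 higher and 140 lower in replicate 2. The direction of this split depended on the scaling, as 46.8% of these calls were higher in replicate 2 with TMM factors, 42.7% of calls with DESeq2 size factors and 52.7% with library totals. A ratio of at least 2-fold was found for 52 genes, 25 higher and 27 lower in replicate 2, and with scaling by library totals the split was 31 and 22. These tests compare the 2 libraries, not conditions.

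Among genes with a mean of at least 100 counts, the lowest ratio was that of Mir26a-2, in an exon of Ctdsp2. It had 1563 counts in replicate 1 and 59 in replicate 2, a log2 ratio of -4.16 (exact binomial test, adjusted p = 1.52e-265). Mir26a-2 shares 25 nt with another microRNA gene, so its ratio covers only reads with a unique place. Mir674, Mir298, Mir31 and Mir140 followed at log2 ratios of -2.28, -2.06, -1.82 and -1.74. Mir298, among the 20 most abundant genes, stood at 29970 CPM in replicate 1 and 7502 CPM in replicate 2. The highest ratios were those of Mir153, a neuronal microRNA in an intron of Ptprn2, at 2.78 (58 and 272 counts), Mir185, in an intron of Tango2, at 2.74 (864 and 3927 counts), Mir1930 at 2.22, Mir505 at 1.73 and Mir200c at 1.62. By mean count, the SD of the log2 ratio was 0.72 for genes with 10 to 100 counts, 0.81 for 100 to 1000, 0.62 for 1000 to 10000 and 0.57 for 76 genes with at least 10000 counts, and the median absolute log2 ratios were 0.45, 0.35, 0.27 and 0.24. Of the 76 genes, 4 differed at least 2-fold.

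**Figure D4:**
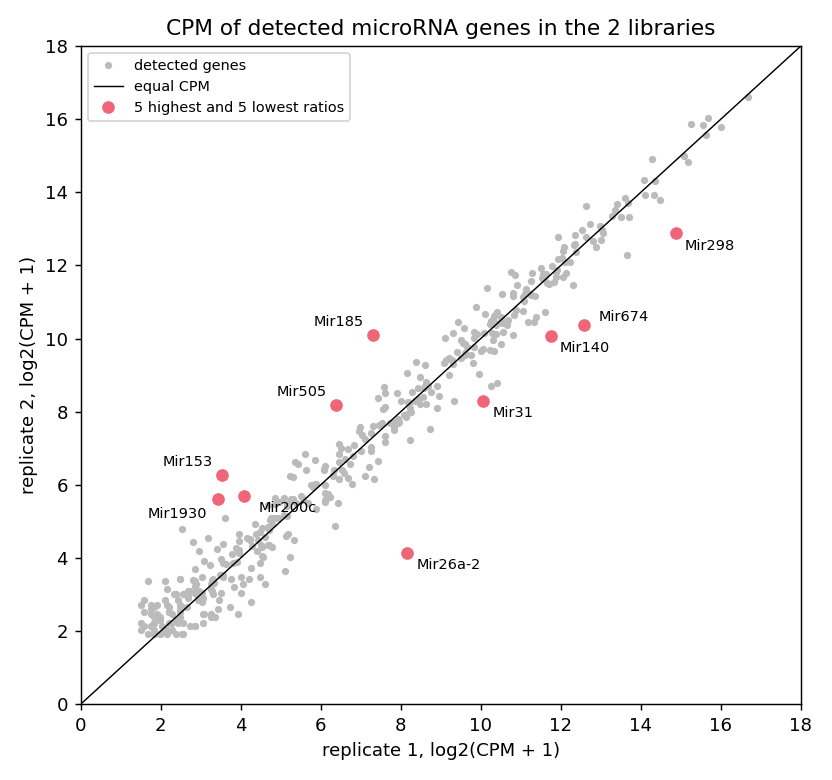
Each point is a detected microRNA gene at its log2(CPM + 1) in replicate 1 (x) and replicate 2 (y), and the line marks equal CPM. The 10 labelled genes have the 5 highest and 5 lowest ratios among genes with a mean of at least 100 counts, and Mir26a-2 lies farthest from the line, with 1563 and 59 counts.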

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

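The search for stretches shared by the Mir124 and Mir9 copies and the comparison of numbered copies with and without such a stretch were set after the data were first examined but before their own results were seen, and the other tests in this part were chosen after the results were seen. The series has a single group, so no biological explanation tied to a group was tested.

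Data outside the sense counts held a signal in both libraries. Antisense counts on microRNA genes numbered 321748 in replicate 1 and 215587 in replicate 2, or 5.63% ± 0.112 of sense plus antisense counts (SD, n = 2). The genes with the most were Gm25927, opposite Mirlet7e, with 112777 and 55715 antisense counts, Gm24083, opposite Mir191, with 54320 and 37070, and Mir126b, opposite the endothelial Mir126a, with 45483 and 28449. Against a loss of strand, or antisense transcription across the annotated genes, genes without a microRNA gene on the opposite strand had 0.00391% of their counts in the antisense column. Of all antisense counts, 99.9% lay in the 64 genes that overlap another microRNA gene on the opposite strand, so these counts may be sense reads of that neighbour, listed again. In both libraries the sense counts of Mirlet7e and Mir191 equalled the antisense counts of Gm25927 and Gm24083, and Mir126a had 45493 and 28455 sense counts. Which strand gives rise to the reads of such a pair rests on the strand column of the files and was not tested in another way.

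Reads that matched several places numbered 6510824 in replicate 1 and 3723576 in replicate 2, more than the sense counts on genes in each. The brain microRNAs Mir124 and Mir9 had few counts on all of their 3 copies each, from 0.877 ± 0.0499 CPM for Mir124a-2 to 58.3 ± 14.6 CPM for Mir9-3 (SD, n = 2). Reads left out because they match several copies could account for this: each of the 6 copies shares at least 26 nt with another microRNA gene, longer than most mature microRNAs, but the 60 numbered copies with any count all share at least 22 nt, abundant ones included, so a comparison with copies that share less was void. Mir128-1 and Mir128-2 share 23 nt and Mirlet7c-2 shares 26 nt, and they hold 6638, 2397 and 3100 CPM. Their transcripts are 70, 76 and 95 nt long, so these counts can come from unshared sequence. They do not show whether reads of the shared stretch were left out. Over the 54 other numbered copies with any count, longer shared stretches went with lower levels at a Spearman rho of -0.24 (permutation test, two-sided p = 0.0759), which missed the threshold. Without the 2 genes farthest from the median length, rho was -0.17. With the 6 genes themselves included, as first computed, rho was -0.35 (permutation test, p = 0.00696). Copies without a count were left out, so copies that may have lost all their reads did not enter any of these values. Low expression and left-out reads cannot be told apart for these 6 genes, since the 41.3% of reads that match several places are not divided by gene in these files.

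The genes with the largest gaps between the libraries were also examined. Of genes with a mean of at least 100 counts, 27 differed at least 2-fold, 10 higher and 17 lower in replicate 2, Mir298, Mir26a-2 and Mir185 among them. A linear trend with the GC content of the precursor is argued against, since it was nearly flat (0.02 log2 units per 10% GC, bootstrap interval -0.04 to 0.09) and at its bound gave these 27 genes at most 0.24, against a median absolute log2 ratio of 1.58. A difference in transcription of whole clusters is also argued against for the 9 genes with a counted neighbour. The neighbours of these genes had a median log2 ratio of -0.12 in the gene's own direction (bootstrap interval -0.26 to -0.07). Values ran from -0.86 for Mir16-1 to 0.30 for Mir222, whose neighbour alone moved in the gene's own direction. Mir673 and Mir665 had the same value, with 11 neighbours each, so the 9 values are not all independent. Mir298, Mir30d and Mir222 were among the genes with only 1 neighbour. For Mir298, at -2.06, the neighbour was Mir296, and the neighbours' value in the direction of Mir298 was -0.06. The other 18 genes, Mir26a-2 and Mir185 among them, had no such neighbour, and for these a difference between the animals, the dissection or the library preparation may be the source and was not tested. Mir26a-2 also shares 25 nt with another microRNA gene, so its ratio covers only reads with a unique place.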

How the results depend on the processing

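The minimum of 5 CPM, which left 360 genes detected, and the search of transcripts for shared stretches (its lengths were planned for the genome) were chosen after seeing the data, and all other settings were planned. The planned search of the genome for unique 20-mers and its correlation with CPM were not run. No paired analysis was possible because there is 1 group.

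A minimum of 1 count in each library gave 670 detected genes and 158 with a 2-fold ratio, any count in either library gave 817 and 305, with a coefficient of variation of 0.346, and a minimum of 100 counts gave 267 and 21, with 0.277 and a Pearson r of 0.977. These settings change which genes enter. Genes past the binomial test numbered 220 to 288, and r lay between 0.977 and 0.987, over the settings of count minimum, strand and scaling, and r also with the pseudocount of 0.1 CPM; neither was computed with the minimum of 5 CPM. DESeq2 size factors and library totals put 42.7% and 52.7% of the genes past the binomial test higher in replicate 2, against 46.8% with TMM, and left 49 and 53 genes at 2-fold, higher and lower in replicate 2 for 21 and 28, and for 31 and 22.

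With all reads as the denominator, shares of assigned reads fell to 0.369 to 0.372 of their value for the 16 lists. Let-7 held 9.59%, Dlk1-Dio3 8.13%, the neuron list 1.19% and the 10 most abundant genes 18.02%. Without Mirlet7b, these lists held 17.6%, 24.4% and 3.59%. Without regard to strand the top 10 held 51.8%, and 10 lists moved by more than their SD, 7 up and 3 down, the latter being the oligodendrocyte, endothelial and erythroid lists. With either replicate left out, let-7 held 24.8% to 27.1% and Dlk1-Dio3 21.4% to 22.6%. Relative to its main value, the muscle list moved most and held 0.00496% to 0.0107%. The antisense share was 3.98% without its leading gene, and clusters within 50 kb held 66.9% of counts. Genes that share at least 18, 20 or 22 nt numbered 1128, 1084 and 1023. Depth limits genes under about 100 counts, where the simulated test missed part of the 2-fold changes.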

Other observations

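All values in this part were chosen after the data were seen.

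Abundant families outside the 16 lists made up a large part of the hippocampal counts. The mir-99 family (Mir99a and Mir99b) held 6.30% ± 1.199 of the counts (SD, n = 2), Mir139 5.94% ± 1.02 and Mir149 2.52% ± 0.773. The mir-23 genes, Mir23a and Mir23b, held 1.90% ± 0.376 and the 7 mir-30 genes 1.54% ± 0.472. The mir-125 genes, led by Mir125a among assigned reads, held 1.48% ± 0.135 and the 6 mir-181 genes 1.30% ± 0.0228. Mir125b-1 and Mir125b-2 each share 24 nt with another microRNA gene, and the Mir30c and Mir181a copies share 28 nt. Reads that match several places are in no gene count, so the levels and order of these families are uncertain. The mir-30 share was 1.88% in replicate 1 and 1.21% in replicate 2, and Mir30d alone had 70640 and 17914 counts, whereas the mir-181 share was 1.29% and 1.32%.

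By position, microRNAs in introns of protein-coding genes held 30.8% ± 1.06 of the counts (SD, n = 2), led by Mir139 in Pde2a, Mirlet7g in Wdr82 and Mir149 in Gpc1, and 24.5% of these genes were detected. Those in exons of non-coding genes held 30.2% in replicate 1 and 27.8% in replicate 2 (SD 1.70), led by Mirlet7b in Lncppara, and 40.8% of them were detected. MicroRNAs without an annotated host gene on their own strand held 23.7% ± 0.0802, led by Mir127 and Mir487b, and 11.2% were detected. Genes on the opposite strand were not considered as hosts, so these microRNAs need not lie outside genes. Introns of non-coding genes held 10.1% ± 0.885 and exons of protein-coding genes 6.395% ± 0.171.

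The choice of strand column decides whether some genes are seen at all. In the counts without regard to strand, 27 detected genes kept under 5% of their sense counts, and these genes held 5.96% ± 0.127 of the sense counts (SD, n = 2). They include Mirlet7e at 18109 ± 3498 CPM, Mir126a at 8144 ± 224 CPM, Mir219a-2 at 1004 ± 345 CPM and Mir9-1 at 16.1 ± 10.5 CPM, each with a microRNA gene annotated on the opposite strand. Mirlet7e had 0 counts in both libraries in that column.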
